A study of Mus musculus with 6 samples.

How the data were processed

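RNA-seq libraries from 6 samples of mouse leukemia cells were compared. Per the labels, the cells were BALB/c bone marrow cells that carried mutant forms of CSF3R, the receptor for granulocyte colony-stimulating factor, and of CEBPA, a transcription factor of the myeloid lineage, delivered by retrovirus. They were grown in medium with serum and treated for 48 h with DMSO, the solvent control, or with 4 nM GSK-LSD1, an inhibitor of the histone demethylase LSD1 (gene Kdm1a). Total RNA was extracted and the libraries were built by a sequencing service, per the labels' protocols. Each group held 3 libraries, assigned by their titles. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

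The values deposited by the authors are a normalised signal, 1 value per gene symbol and library. From the values themselves they are gene read counts divided by a scaling factor per library: the low values of each library are whole multiples of its smallest value, which lay between 0.973 and 1.04. STAR and DESeq2 and the builds mm10 and GRCm38 are named in the submitters' processing notes, without version, role or order. The program that counted reads, its annotation, its treatment of strand and any filter on genes are not given in the sources used here. The table had 15035 rows, and 22 gene symbols had been turned into dates by a spreadsheet. Those rows were kept in the tests and are not named. All 6 columns of values belonged to a labelled sample.

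The total of the scaled values was between 9877460 and 10107900 per library. If the smallest value of a library stands for 1 read, the libraries held between 9572640 and 10199500 counted reads. Between 13879 and 14106 genes had a value above 0, and the 10 most abundant genes took 4.96% to 5.13% of the total. The values of libraries of the same group, divided by the smallest value, differed by more than sampling noise, and the 6 libraries were counted as separate samples. Over genes with a sum of at least 20, the chi-square per degree of freedom was 2.52 to 3.51 between DMSO libraries. It was 1.57 to 1.86 between GSK-LSD1 libraries and 17.7 to 20.1 between groups. The DMSO libraries thus differed more, while the main test, given below, fits 1 variance per gene to both groups.

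Genes were tested where the value was at least 10 in at least 3 of the 6 libraries, which kept 11588 genes and left out 3447. The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with a mean-variance trend in the empirical Bayes step, without a replicate term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, GSK-LSD1 against DMSO, and understate the change of genes with low values. Counts of larger changes used a fitted log2 fold change of at least 1 in either direction. Count models were not used. They were planned only where each library met a criterion for whole reads, which asks that the smallest value stand clear of 1, and DMSO replicates 2 and 3 (0.991 and 0.995) did not meet it, although their low values are also whole multiples of the smallest.

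Before the data were examined, 26 gene lists were fixed from general knowledge of myeloid leukemia cells, LSD1, JAK/STAT signalling, other blood and stromal cell types and RNA quality. The 24 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Member genes were also counted with p-values adjusted over the list alone. Across the lists, 12 genes stood in more than 1 list. The genes named were also fixed by rule before the data were examined. They were Kdm1a, Csf3r and Cebpa. They were also the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean value of at least 50, no overlap between the groups and a gene name rather than a model number. From each list up to 4 members in each direction were taken, with the members of the LSD1 complex, myeloid transcription factor and JAK/STAT lists in full where useful. Where genes were named outside this rule, the text says so. Not every gene that the rule selects is reported here.

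The test was checked on simulated values for this comparison, drawn from the means of the real libraries over about 11551 tested genes with 200 genes changed per run, in 5 runs. It recovered 72.4% of genes changed by 1.25-fold, 90% at 1.5-fold, 99.2% at 2-fold and 100% at 4-fold, with 6.1% false calls. The 200 genes were drawn above a minimum mean value, so recovery at the lowest values tested is not covered. The cholesterol synthesis list was lowered in addition, and its calls count among all calls in the false-call rate. Each simulated gene had the same dispersion, 0.000342, the median over the real genes, whereas real genes differ in spread. Far fewer genes were changed than were called in the real comparison. These rates describe the simulated setting and may be better than those in the real libraries. Gene positions were taken from GENCODE M21 on GRCm38, where 14439 of the 15035 symbols were found. Of 234 genes considered for naming, 33 share exon bases with another gene of the table, among them Gse1, Nab2, Junb, Ctsb, Ccnd3, Ifi47, Shmt2, Lss, Alas2, Rag2, Zeb2, Stat3 and Pfkp, and their values are uncertain to that extent. The alternatives were other pseudocounts, filters on low values, TMM and quantile scaling, other variance models, a replicate term, each library left out in turn, and, for lists, camera with an estimated correlation and fry. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.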

Results

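Gene expression was measured by RNA-seq in mouse bone marrow leukemia cells carrying mutant CSF3R and CEBPA, in 3 libraries from cells given DMSO and 3 from cells given 4 nM GSK-LSD1 for 48 h. The series is titled for combined inhibition of the JAK/STAT pathway and LSD1 in this form of acute myeloid leukemia, and the 1 comparison in its design asks which genes differ after the LSD1 inhibitor alone. The libraries held between 9572640 and 10199500 counted reads, taking the smallest value of a library as 1 read. All values are scaled read counts, given as mean ± SD with n = 3 libraries per group.

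After 48 h of GSK-LSD1, genes of later neutrophil granules and of monocytes rose together with the repressor genes Gfi1 and Gfi1b, while most genes listed for cell growth, DNA replication, cholesterol synthesis and the red cell lineage fell. Clu, which encodes the secreted chaperone clusterin, rose from 522 ± 37.4 to 8613 ± 233, a 16.5-fold difference. Gfi1b rose 7.43-fold and the neutrophil collagenase gene Mmp8 6.56-fold, while Themis, best known from T cell development, was 10.7-fold lower. In all, 2389 genes were higher and 2373 lower with GSK-LSD1 by limma with Benjamini-Hochberg adjustment, together 41.1% of the 11588 tested, and 5613 genes had an unadjusted p under 0.05. Large changes were mostly rises: 523 genes were at least 2-fold higher and 113 at least 2-fold lower, so that 82.2% of these were rises, and 69.9% under quantile scaling. The median log2 fold change of all tested genes was -0.01, which a scaling factor per library can bring near 0 by itself. The first principal component, with 77.1% of the variance, separated the groups.

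**Figure D1:**
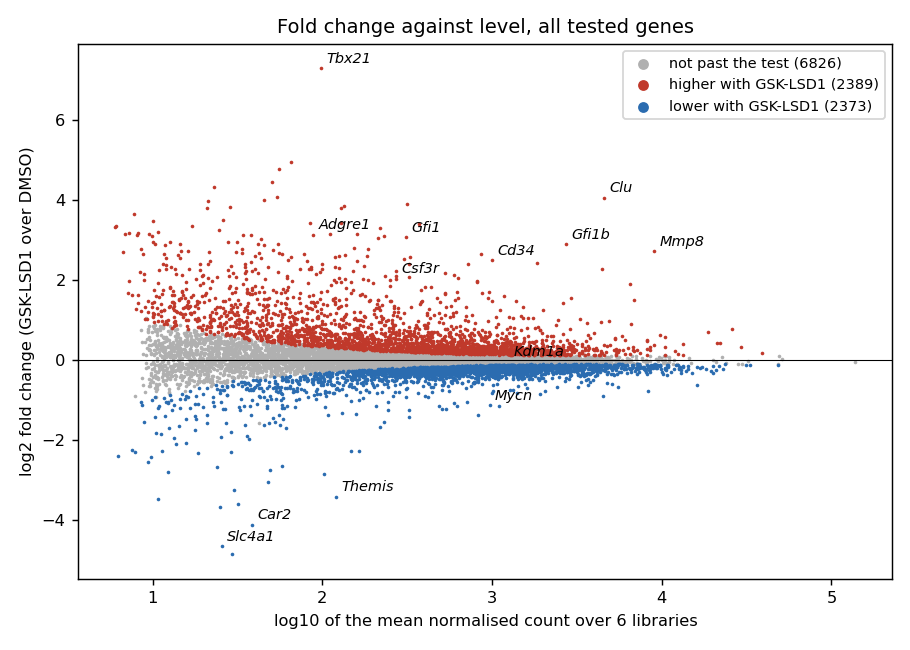
Log2 fold change (GSK-LSD1 against DMSO, vertical axis) of each of the 11588 tested genes against the log10 of its mean scaled read count over the 6 libraries (horizontal axis), with genes past the limma threshold in red (higher) or blue (lower) and the rest in grey. Of the genes past the threshold, 523 were at least 2-fold higher and 113 at least 2-fold lower, and Tbx21, Clu, Gfi1 and Gfi1b lie among the largest rises.

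By the naming rule, the gene with the largest rise was Tbx21, which encodes the transcription factor T-bet of T and NK cells (chromosome 11, 97098071 to 97115331, GRCm38). In units of the smallest value it had a count of 1 over the 3 DMSO libraries and 581 over the 3 GSK-LSD1 libraries, a ratio of 602 with a 95% counting interval of 108 to 23805. Mamdc2 rose from 3.30 ± 1.52 to 128 ± 31.9, Slc15a3 from 3.62 ± 3.03 to 107 ± 13.4, Ifi202b from 3.63 ± 1.53 to 97.4 ± 23.4 and Il1f9, a cytokine of the interleukin 1 family, from 5.26 ± 1.45 to 103 ± 8.40. The remaining genes of the 12 with the largest rise by the naming rule were Cdc42bpb, Scara3, Scpep1, Fstl1, Moxd1 and the neuronal tubulin gene Tubb3, with Clu (chromosome 14, 65968483 to 65981547), and their log2 fold changes were between 3.40 and 4.04. Themis fell from 220 ± 15.7 to 20.7 ± 8.04 (chromosome 10, 28668360 to 28883818), Col11a1 from 178 ± 25.4 to 25.5 ± 10.7 and Tnfrsf9, a costimulatory receptor, from 274 ± 34.0 to 56.4 ± 10.1. Dcbld2 and Slco2b1 fell, with log2 fold changes of -2.66 and -2.28. The fall was smaller for Il10, Thy1, Chpf, Eno2, Kel, Crisp1 and B4galnt2, with log2 fold changes from -1.72 to -1.45. Reads of Ifi202b can be shared with close relatives in its gene cluster. Exons of Slc15a3, Scpep1 and Dcbld2 overlap a gene on the other strand (Tmem132a, Scpep1os and St3gal6), and the treatment of strand in counting is not known, so the values of these genes are uncertain.

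The gene of the drug target, Kdm1a (chromosome 4, 136550540 to 136602723), was 1257 ± 59.6 with DMSO and 1227 ± 16.3 with GSK-LSD1, a log2 fold change of -0.03 with a standard error of 0.0518 (adjusted p = 0.631 by limma with Benjamini-Hochberg adjustment). Csf3r (chromosome 4, 126024550 to 126044440) rose 4.08-fold, from 106 ± 12.8 to 434 ± 14.6 (adjusted p = 4.14e-19 by limma with Benjamini-Hochberg adjustment). Cebpa (chromosome 7, 35119293 to 35121928) was 4437 ± 562 and 4332 ± 49.0, with a log2 fold change of -0.03 (adjusted p = 0.734), and without DMSO replicate 3 its value was -0.13 with an adjusted p of 0.00860. The labels do not give the sequence of the retroviral CSF3R and CEBPA, so reads of the transgenes and of the mouse genes are not separated in these values.

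Among 16 genes of the LSD1 complex and its partners, 5 rose, 3 fell and 8 were not past the threshold, adjusted over all genes tested and likewise adjusted over the list alone. Gfi1 (chromosome 5, 107716657 to 107726036) and Gfi1b (chromosome 2, 28609450 to 28621982), which encode DNA-binding repressors that recruit LSD1, rose from 65.5 ± 5.42 to 553 ± 13.4 and from 646 ± 24.6 to 4800 ± 162. The other changes were smaller: the log2 fold change was 0.50 for Phf21a, 0.34 for Gse1, 0.31 for Zmym2 and -0.28 for Rcor2, while Hdac1 and Ctbp2 lost their call when single libraries were left out. The list was higher by camera (adjusted p = 0.0245), but not with an estimated correlation (adjusted p = 0.146) nor, in a test added after the values were seen, without Gfi1 and Gfi1b (adjusted p = 0.503).

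Of 26 tested myeloid transcription factor genes, 14 rose, 3 fell and 9 did not pass. Adjusted over the list alone, 14 rose and 4 fell. Besides Gfi1 and Gfi1b, Klf2 rose from 39.2 ± 7.08 to 199 ± 22.7, Fos from 31.0 ± 5.0 to 83.8 ± 4.56 and Irf8, a regulator of monocyte and dendritic cell fate, from 33.2 ± 2.73 to 79.4 ± 7.44. Zeb2 rose 1.87-fold, Cebpe, a factor of late neutrophil maturation, 1.54-fold and Spi1, which encodes PU.1, 1.17-fold. Nab2 and Junb fell, with log2 fold changes of -0.72 and -0.36. Runx1 and Cebpb had log2 fold changes of -0.01 and 0.05 and were not past the threshold. The list was higher by camera (adjusted p = 0.000145) but not with an estimated correlation (adjusted p = 0.0838).

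**Figure D2:**
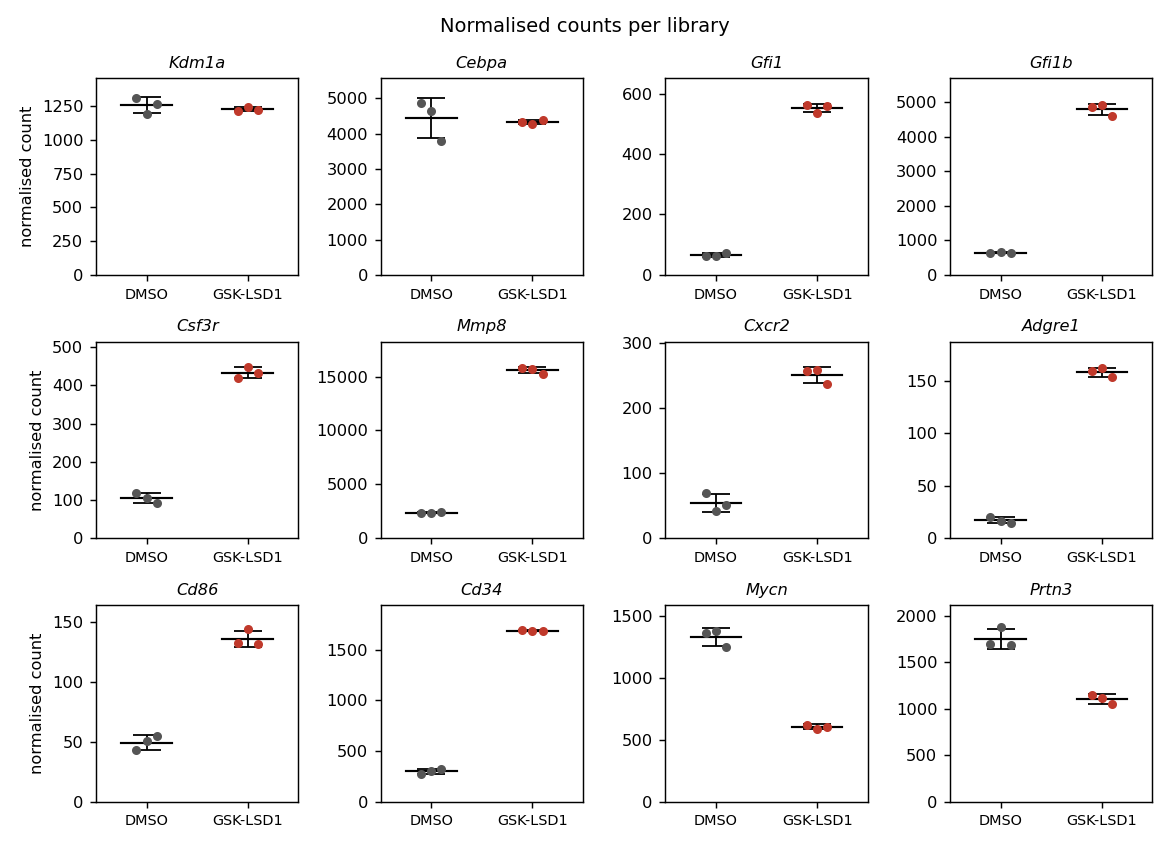
Scaled read counts (vertical linear axes from 0, one panel per gene) of 12 named genes in each of the 3 DMSO (grey) and 3 GSK-LSD1 (red) libraries, where each point is 1 library, long lines are group means and short lines mean ± SD. Gfi1b is near 646 with DMSO and 4800 with GSK-LSD1 and Mmp8 near 2376 and 15579, while Kdm1a has means of 1257 and 1227.

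Of 19 tested genes of secondary and later granules and mature neutrophils, 17 rose and 2 fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.16 (camera adjusted p = 1.41e-14). Mmp8 rose from 2376 ± 61.2 to 15579 ± 296, Mmp9, the gelatinase gene, from 9.22 ± 1.56 to 74.0 ± 0.848, and the chemokine receptor gene Cxcr2 from 53.9 ± 14.1 to 251 ± 12.4. S100a9, named after its values were seen, rose 2.89-fold. The 2 that fell were Ngp (-1.25 on the log2 scale) and Chil3 (-0.35). Of 12 genes listed for primary granules, which are made at the promyelocyte stage, 3 rose, 7 fell and 2 did not pass. Adjusted over the list alone, 8 fell. Not all of the listed genes encode granule proteins. Ms4a3 fell 2.21-fold, Elane, the neutrophil elastase gene, 1.89-fold and Prtn3 1.59-fold, while Mpo rose from 7390.3 ± 377 to 8952 ± 164. The primary granule list was lower by camera (adjusted p = 0.047), with an adjusted p of 0.283 with an estimated correlation. Its call was also lost without DMSO replicate 2 (adjusted p = 0.0638), DMSO replicate 3 (0.0534) or GSK-LSD1 replicate 3 (0.0516), with quantile scaling (0.0925) and among genes with a mean value of at least 50 (0.0702).

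Monocyte and macrophage genes rose in the same libraries: 20 of 25 tested members were higher, 2 lower and 3 not past the threshold, and 3 were lower adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 8.25e-11). Adgre1, which encodes the macrophage marker F4/80, rose from 17.4 ± 2.83 to 158 ± 4.40, the protease gene Ctss from 47.4 ± 7.39 to 326 ± 38.9, and Mpeg1 from 51.7 ± 12 to 313 ± 9.40. Itgam, which encodes CD11b, and the lysozyme gene Lyz2, both named after their values were seen, rose 3.53-fold and 4.14-fold. Cd300a and Ctsb fell, with log2 fold changes of -0.66 and -0.28. Of 25 phagocyte oxidase and pattern recognition genes, 18 rose, none fell and 7 did not pass, or 19 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.17e-06). The formyl peptide receptor genes Fpr1 and Fpr2 rose from 2.30 ± 0.545 and 4.95 ± 4.57 to 31.9 ± 0.275 and 44.1 ± 6.0, and Nlrp3 and Clec7a rose 6.79-fold and 6.69-fold. This call was lost among genes with a mean value of at least 50 (adjusted p = 0.0702), which leaves out Fpr1, Fpr2 and Nlrp3, and the list median was then 0.19 in place of 0.75. Of 7 tested dendritic cell and antigen presentation genes, 2 rose and 5 did not pass, by either adjustment. The costimulatory gene Cd86 rose from 49.4 ± 5.97 to 136 ± 6.88 and Cd74 from 21.7 ± 0.840 to 40.2 ± 9.91. The list median was -0.03, its mean 0.29, and camera gave the upward direction with an adjusted p of 0.492. That median turned to 0.0105 without DMSO replicate 3, 0.0334 without GSK-LSD1 replicate 2 and 0.227 without the filter on low values.

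Stem and progenitor genes changed in both directions, with 6 higher, 8 lower and 4 not past the threshold of 18 tested, by either adjustment. Cd34, a surface marker of progenitors, rose from 299 ± 28.5 to 1685 ± 4.38, although its exons overlap a gene model on the other strand. Sox4 rose 1.73-fold. Mycn fell from 1328 ± 69.8 to 604 ± 19.3, and Lmo2, Angpt1 and Adgrg1 fell, with log2 fold changes of -0.72, -0.45 and -0.38. The list median was -0.10 and its mean 0.08, with a camera adjusted p of 0.46. Without GSK-LSD1 replicate 1 the median was 0.0053. Of 22 JAK/STAT target genes, 7 rose, 6 fell and 9 did not pass, by either adjustment. Bcl6, which STAT5 represses, rose from 57.0 ± 8.69 to 139 ± 12.5 and Ptpn6, which encodes the phosphatase SHP-1, rose 1.34-fold. Fos, Id1, Ccnd2, Socs3 and Il4ra also rose, with log2 fold changes of 1.42, 0.70, 0.24, 0.17 and 0.13. The calls of Socs3 and Il4ra were lost in at least 1 alternative. Ccnd3 fell from 3763 ± 116 to 2835 ± 29.9, and Socs2, Pim2 and Myc fell with log2 fold changes of -0.20, -0.26 and -0.22. Gadd45g (-0.44) and Junb (-0.36) fell as well. Pim1 (log2 fold change -0.08), Cish (-0.06), Socs1 (-0.05), Bcl2l1 (0.01), Osm (-0.02) and Stat3 (0.05) were not past the threshold. The list median was 0.01, its mean 0.12 and the direction from camera was down, with an adjusted p of 0.961. The median turned negative, to -0.0132, with quantile scaling. It was also below 0 at a mean value of at least 50 and without DMSO replicate 1, DMSO replicate 3 or GSK-LSD1 replicate 1.

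Interferon-stimulated genes did not pass as a list (camera adjusted p = 0.492), with 6 of 24 tested members higher, 4 lower and 14 not past the threshold by either adjustment. Zbp1 rose 2.17-fold and Gbp2 1.87-fold, while Ifi47 and Ifih1 fell with log2 fold changes of -0.56 and -0.40. Of 18 inflammatory cytokine and NF-kB genes, 6 rose, 3 fell and 9 did not pass, again by either adjustment (camera adjusted p = 0.503). Il6 rose from 759 ± 85.5 to 1342 ± 18.6 and Ccl3 from 4.28 ± 1.54 to 16.1 ± 1.66, and the lectin gene Clec4e fell from 3129 ± 127 to 2291 ± 137. Of 14 immediate stress genes, which mark handling of cells, 5 rose, 5 fell and 4 did not pass by either adjustment. Their median was -0.02, their mean 0.23 and the direction from camera was up (adjusted p = 0.503). The median turned to 0.03 without DMSO replicate 2, 0.0058 without GSK-LSD1 replicate 1 and 0.239 without the filter on low values. Zfp36 rose 2.17-fold, Jun 1.87-fold and Hmox1 1.68-fold, while Junb and the heat shock gene Hsph1 fell, with log2 fold changes of -0.36 and -0.23.

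Genes of growth and DNA synthesis fell by small amounts. Of 30 MYC target and ribosome biogenesis genes, 28 fell, none rose and 2 did not pass, and all 30 fell when adjusted over the list alone (median log2 fold change -0.30, camera adjusted p = 9.51e-14). Ldha, the lactate dehydrogenase gene, fell 1.55-fold, the polyamine synthesis genes Srm and Odc1 fell 1.44-fold and 1.35-fold and Nolc1 fell 1.32-fold. Of 47 cytosolic ribosomal protein genes, 39 fell, none rose and 8 did not pass, or 43 fell adjusted over the list alone. Rps20 fell 1.28-fold and Rplp1 1.2-fold. The median of this list was -0.19 (camera adjusted p = 3.6e-11, but adjusted p = 0.198 with an estimated correlation), and reads of these genes can be shared with their many pseudogenes. Of 30 genes of the G1/S transition and DNA replication, 23 fell, none rose and 7 did not pass, or 26 fell adjusted over the list alone (median -0.21, camera adjusted p = 9.35e-08). Cdt1 fell 1.34-fold, the helicase gene Mcm3 1.29-fold and Pcna 1.26-fold. Of 28 G2/M and mitosis genes, 3 rose, 10 fell and 15 did not pass, or 11 fell adjusted over the list alone. Aurkb and Birc5 fell, with log2 fold changes of -0.26 and -0.25, Nusap1 rose with 0.23, and the list missed the threshold (camera adjusted p = 0.0568). It passed without DMSO replicate 1 (0.0425), DMSO replicate 2 (0.0243) or GSK-LSD1 replicate 1 (0.0491), and without the filter on low values (0.0279), while with an estimated correlation its adjusted p was 0.509. Of 19 p53 target and CDK inhibitor genes, 5 rose, 4 fell and 10 did not pass by either adjustment (camera adjusted p = 0.534). Trp53inp1 rose from 187 ± 33.4 to 386 ± 26.0 and Cdkn1b, which encodes the inhibitor p27, from 421 ± 16.9 to 581 ± 45.9.

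Cholesterol synthesis genes fell nearly as a block: 21 of 23 were lower, none higher and 2 not past the threshold, by either adjustment (median log2 fold change -0.38, camera adjusted p = 2.61e-14). Pmvk fell from 328 ± 19.8 to 159 ± 30.7, Fdps from 1997 ± 139 to 1226 ± 91.5, Lss 1.56-fold and Idi1 1.54-fold. Of 24 genes of the integrated stress and unfolded protein responses, 3 rose, 12 fell and 9 did not pass, or 4 rose and 14 fell adjusted over the list alone. Asns, the asparagine synthetase gene, fell from 1919 ± 73.0 to 1415 ± 36.6, Vldlr 1.82-fold and Shmt2 1.27-fold, while Slc7a11 rose 1.24-fold. This list was lower by camera (adjusted p = 0.0154), but not with an estimated correlation (adjusted p = 0.283) or quantile scaling (adjusted p = 0.0725).

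Genes of other blood lineages also differed. Of 12 tested erythroid genes, 10 were lower, none higher and 2 not past the threshold, by either adjustment (median log2 fold change -2.31, camera adjusted p = 4.99e-07). Slc4a1, the band 3 anion exchanger gene, fell from 49.8 ± 8.82 to 1.32 ± 1.48, Car2 from 72.2 ± 9.46 to 4.73 ± 5.64 and Alas2, the first enzyme of erythroid heme synthesis, from 41.8 ± 1.54 to 5.74 ± 1.31. The transcription factor genes Gata1 and Nfe2, which are also active in megakaryocytes and were named after their values were seen, held most of the list's summed value. Gata1 fell 1.22-fold, from 665 ± 28.7 to 547 ± 14.4, and Nfe2 was 1263 ± 61.6 and 1229 ± 17.9, not past the threshold. The list took 0.0231% of the total value with DMSO and 0.0189% with GSK-LSD1. Of 8 tested megakaryocyte and platelet genes, 5 rose, 2 fell and 1 did not pass by either adjustment. Itgb3 rose from 657 ± 15.0 to 1571 ± 99.4 and the thrombin receptor gene F2r from 3284 ± 28.6 to 6453 ± 135, while Itga2b fell by 0.21 on the log2 scale. This list was higher by camera (adjusted p = 0.00474), but not with an estimated correlation (adjusted p = 0.196) or without the filter on low values (adjusted p = 0.202). Without that filter the list median turned from 0.53 to -0.11. Of 16 mast cell, basophil and eosinophil genes, 6 rose, 2 fell and 8 did not pass, or 9 rose adjusted over the list alone. Cpa3, the mast cell carboxypeptidase gene, rose from 14320 ± 982 to 23028 ± 597, Cd200r3 2.80-fold and Tpsab1, whose reads can be shared with a close relative, from 1.64 ± 1.5 to 44.4 ± 0.463. Hdc, the histamine-producing enzyme gene, fell from 673 ± 25.7 to 302 ± 13 and Fcer1a fell 1.28-fold. The list was higher by camera (adjusted p = 0.0473), with an adjusted p of 0.198 with an estimated correlation. Its adjusted p was 0.0584 without DMSO replicate 2 and 0.0892, 0.156 and 0.14 without GSK-LSD1 replicates 1, 2 and 3. Among genes with a mean value of at least 50 it was 0.146, with a list median of 0.13 in place of 0.23.

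Lymphoid and stromal lists held few tested members. Of 4 tested B lymphoid genes, too few for the list test, Cd22 rose from 5.62 ± 3.79 to 37.6 ± 4.64, Rag2 fell from 48.1 ± 10.1 to 20.9 ± 3.77 and 2 did not pass, by either adjustment. Of 6 tested T and NK cell genes, 2 rose, 1 fell and 3 did not pass by either adjustment (camera adjusted p = 0.345). Tbx21 and Gzma rose, Gzma 1.21-fold, and the kinase gene Lck fell 1.46-fold. Of 5 tested stromal and endothelial genes, 4 rose and 1 fell by either adjustment (camera adjusted p = 0.456). Acta2 rose from 1.97 ± 1.98 to 18.7 ± 10.1, the platelet and leukocyte adhesion gene Pecam1 1.18-fold, and Thy1 fell from 332 ± 24.8 to 103 ± 15.8. Mitochondrially encoded genes were not analysed here. Of the 24 lists tested, 7 were higher and 7 lower by camera with the preset correlation. With an estimated correlation the later granule, monocyte, phagocyte, G1/S, MYC, cholesterol and erythroid lists were past the threshold, with adjusted p between 0.0224 and 0.0326. The estimate was below the preset 0.01 for the LSD1 complex list (-0.0313), whose call was lost. A lost call therefore need not mean that the members of a list vary together.

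**Figure D3:**
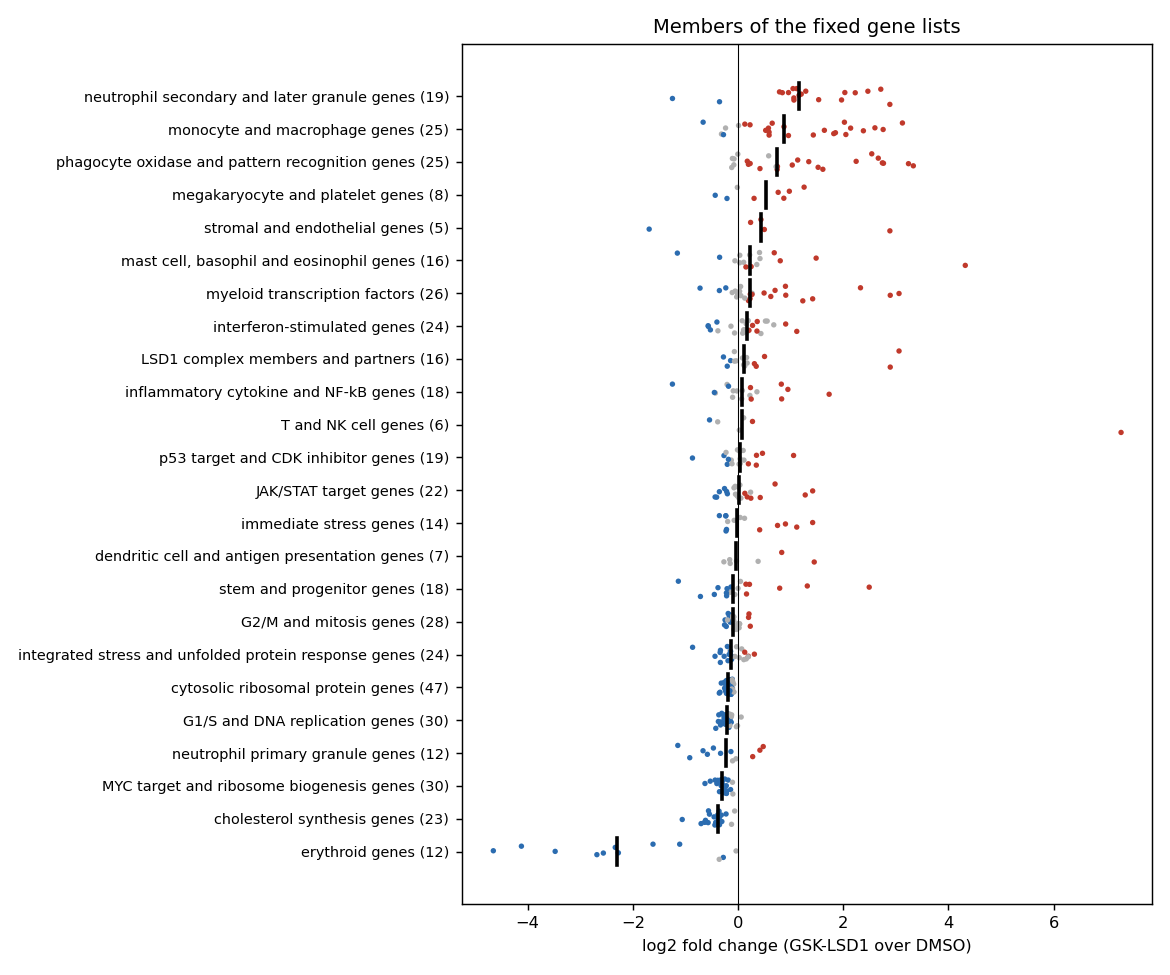
Log2 fold changes (horizontal axis, GSK-LSD1 against DMSO) of the tested members of each fixed gene list, where each point is 1 gene (red higher, blue lower, grey not past the threshold), black bars are list medians and the number of tested members follows each list name. Medians run from -2.31 for erythroid genes to 1.16 for secondary and later granule genes, with cholesterol synthesis at -0.38 and monocyte and macrophage genes at 0.87.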

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

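The fits without Gfi1 and Gfi1b in their lists were chosen after the result was seen, and the other alternatives were fixed before the data were examined. The edgeR and DESeq2 tests planned for recovered whole reads were not run, because DMSO replicates 2 and 3 did not meet the criterion set for whole reads. Among the genes considered for naming, none that was past the threshold changed sign, and no called list changed its camera direction, but the median of the megakaryocyte list turned from 0.53 to -0.11 without a filter on low values, where its call was lost. Some lists that were not called had medians near 0 that changed sign in some alternatives. They were the stem and progenitor, dendritic cell, JAK/STAT, immediate stress, inflammatory and p53 lists. Genes considered for naming that were past the threshold in neither fit changed sign 22 times. Genes at least 2-fold lower numbered 74 with a pseudocount of 8, 219 without a filter on low values, 40 among genes with a mean value of at least 50 and 173 with quantile scaling, against 113. Genes at least 2-fold higher numbered 259 at a mean value of at least 50, against 523, where fewer genes were tested. Camera with an estimated correlation called 3 lists higher and 4 lower, and fry, which does not compare a list with other genes, called 13 higher and 8 lower, against 7 and 7. Leaving out each library in turn gave 1938 to 2363 genes higher, 1951 to 2262 lower, 403 to 540 at least 2-fold higher, 83 to 120 at least 2-fold lower, 6 to 7 lists higher and 6 to 8 lower. Of the 4762 genes called, 4722 kept their call with TMM scaling, 4179 with quantile scaling and 3472 without a mean-variance trend; the cause was not tested. Of 193 genes past the threshold among those considered for naming, 171 kept their call in each alternative that tested them and 22 lost it in at least 1. Many of these genes were picked for large changes or after their values were seen, so they do not represent all calls. Among genes considered for naming that were not past the threshold, 6 gained a call in at least 1 alternative. Low values limit fold changes of genes such as Tbx21. With a replicate block, 2345 genes were higher and 2316 lower, 4635 of the 4762 calls were kept, and the G2/M list reached an adjusted p of 0.0494. Samples that share a number did not deviate together (correlations of -0.0241, -0.0276 and -0.00771), and no sample correlated best with its own number in both directions.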

Other observations

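The tests of hypoxia and neuronal gene lists were run on lists written after related genes had been seen to change, without those genes, and the tests of scaling for the 2-fold counts and of fewer erythroid cells were chosen after the result was seen. Genes named in this part outside the naming rule were chosen after their values were seen.

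Genes of glycolysis and of the response to low oxygen fell with GSK-LSD1. The lactate exporter gene Slc16a3 fell from 1192 ± 98.7 to 459 ± 7.49, Ak4 2.70-fold, Ndrg1 2.57-fold and Bnip3 2.36-fold, and these genes, with Eno2, Gapdh and Ldha, prompted a list of 40 other genes of the same processes. Of its 36 tested members 31 fell, 1 rose and 4 did not pass the limma test with Benjamini-Hochberg adjustment, with a median log2 fold change of -0.47. Pfkp fell 1.82-fold, Pdk1, a kinase that limits entry of pyruvate into mitochondria, 1.75-fold, the glucose transporter gene Slc2a1 1.72-fold and Vegfa 1.52-fold, while Pfkfb4 rose 2.19-fold. Fth1, the ferritin heavy chain gene, rose from 19235 ± 1040 to 32781 ± 538.

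Some genes of mast cells, basophils and cytotoxic granules had high values with DMSO and others had low ones, and no list test was made of these levels. Gzmb, the granzyme B gene, had the second highest mean value of the table, at 50747 ± 3122, and was 51524 ± 579 with GSK-LSD1, a log2 fold change of 0.02 that was not past the threshold. Cpa3 ranked 38, Gata2 215, Fcer1a 218, Slc18a2 382, Cma1 431, Il1rl1 512 and Mcpt8 668 by mean value with DMSO. Lower mean values were found for Prss34 (426), Ms4a2 (253), Kit (29.6), Tpsb2 (20.8), Tpsab1 (1.64) and the perforin gene Prf1 (0.986). Siglecf was at 38.2, Ccr3 at 15.8 and Il5ra at 4.61. Cma1 was 3817 ± 112 and 3903 ± 39.2, with a log2 fold change of 0.03 that was not past the threshold. Eosinophil genes Epx and Prg2 were at 1.32 and 0.662 with DMSO, and the T cell gene Cd3d was at 0.991.

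The fall of hypoxia response and glycolysis genes may be a coordinated change. Without its prompting genes, the list had a camera p of 1.15e-15, and of 0.0146 with an estimated correlation. Genes of the same processes had already been seen to fall in these libraries, so these unadjusted p-values are not independent support. A bias of GC content or transcript length is argued against, since the share of 10000 random lists matched on mean value, GC content and length with a median as low was 1e-04, the smallest this draw can give. The highest median under TMM and quantile scaling was -0.47, so the list fell relative to other genes under both. Both scalings assume little change in the bulk of genes, so a shift shared by all genes cannot be seen. Whether oxygen in the cultures, cell density or LSD1 itself lowered these genes was not tested, and the labels give no measure of these.

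More genes rose than fell by at least 2-fold, and the ratio of 4.63 could come from scaling or from low values. The lowest ratio under TMM and quantile scaling was 2.32, and the ratio among genes with a mean value of at least 50 was 6.48, both above 1.5. The second value argues against low values as the whole source. The choice among these scalings does not account for the whole ratio either. Both scalings assume little change in the bulk of genes, so a shift shared by all genes cannot be seen. The design leaves inhibition of LSD1, a corepressor enzyme, as an open biological explanation that was not tested further.

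The erythroid list fell with a median log2 fold change of -2.31, mostly in genes with low values, while Nfe2 and Gata1, which hold most of its summed value, had -0.04 and -0.28. Low values alone are argued against, since the share of 10000 random lists matched on mean value with a median as low was 1e-04, the smallest this draw can give. A smaller number of erythroid cells in the treated cultures may also lower these genes. Log2 fold changes of the tested members spanned 4.61 and differed beyond their errors (p = 7.13e-92, a chi-square test of heterogeneity across genes). So 1 common factor does not account for all of them. Nfe2 and Gata1, also active in megakaryocytes, were among these members, so this spread cannot decide whether erythroid cells were fewer. No tested member passed the threshold upward, and fewer erythroid cells together with other changes cannot be told apart from lower expression per cell in these bulk libraries.

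A list of 50 neuronal genes without Tubb3, of which 11 were tested, gave a camera p of 0.0499 upward and a p of 0.164 with an estimated correlation, and 0.168 of matched random lists had a median as high, so a rise of neuronal genes stays undecided. Among the 10 splits of the 6 libraries into 3 and 3, the real split was the 1 with the most gene calls, 4762 against at most 1 in another split. It had 636 calls at 2-fold against at most 1. By camera with the preset correlation it had 14 lists, and each of the other splits also called lists, from 5 to 10. With 10 splits the share cannot fall under 0.05. Each of the other splits has 2 libraries of 1 group beside 1 of the other on each side. The difference between the groups then adds to the spread within each side, which lowers gene calls. Part of that difference also remains between the sides and may give list calls. These counts therefore do not show how many calls chance alone would give.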
